A study of Nicotiana tabacum with 4 samples.

How the data were processed

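Total RNA of tobacco seedlings was labelled with Cy3 in 1 colour and hybridized to Agilent tobacco 4x44k arrays, per the labels. There were 2 arrays of vector control and 2 of OpAP2-3 overexpression, and groups and replicate numbers were taken from the sample titles. All 4 arrays lay on 1 slide, with the vector control at positions 1 and 2 and OpAP2-3 at positions 3 and 4, so position and group cannot be told apart.

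The deposited scanner files hold spot intensity, background-corrected by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers. The deposited flags, per the file headers, are other values of 0 or 1 that mark spots well above background, saturated spots and outliers. The authors' value table holds log2 values. Compared with the scanner files, each of its columns equalled log2 of the processed intensity minus a constant, within 0.001 for 100% of probes, and the constants of 11.344, 11.223, 10.993 and 10.746 were close to the 75th percentile of each array. Its medians were -3.24 and -3.19 for vector control and -3.18 and -3.08 for OpAP2-3, its values are not centred per gene, and it runs in the direction of the intensity. The signal at the 75th percentile was 2611 and 2401 for vector control and 2049 and 1723 for OpAP2-3.

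The log2 processed intensity minus each array's 75th percentile was the main measurement. Control spots and outlier-flagged spots were left out and spots of the same probe were averaged. The arrays held 43803 non-control spots of 43759 probes, of which 6635 had an informative description and 16014 were described as unknown. Gene names are those of the array's design. Of the probes, 0 matched an accession and 2 a symbol of the supplied gene table, so the names of the files were kept and no position in the genome is given. A probe was tested if it was well above background on both arrays of at least 1 group.

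Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05, and the median total degrees of freedom was 3.41. Tested on simulated data of 36443 probes for this comparison, 20% of 100 probes changed by 1 on the log2 scale and 81% of 100 changed by 2 were recovered, with 8 false calls. No other simulated probe was changed, while 55.7% of tested probes passed in the data. The adjustment was therefore stricter in the simulation, and these shares do not measure recovery in the data. Gene lists were regular expressions over descriptions. They were tested with camera on the moderated statistics converted to z scores, with a preset correlation of 0.01, 1 probe per gene (the brightest) and at least 5 genes. The 5502 annotated genes tested were the background, a choice the plan left open and made after the files were seen, and all 33442 tested genes were an alternative. On simulated data, camera called a list of 40 genes that had been shifted by 0.3 and did not call an unshifted list of the same size. Nearly all other simulated genes were unchanged, unlike in the data, so this does not measure how well camera finds such a shift there. The simulated genes were also independent, so this does not show how camera treats lists of correlated genes. Some entries were matched by a word and not by function: the receptor-like protein EILP in the ethylene list, plastoglobulin in the seed storage list and host proteins in the viral list, which holds no viral gene.

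The rule for naming genes was fixed before the data were examined. The named genes are the 12 annotated probes with the largest increase and the 12 with the largest decrease, 1 per gene and description. These were taken among probes past the threshold whose arrays did not overlap between groups. Up to 4 members of each described list with the smallest p were also named. Every probe has a gene name, so annotated was read as having an informative description once the files were seen.

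Alternatives fixed before the data were examined were normexp background correction with offset 50, quantile normalization, median scaling, the authors' table, no filter, a filter on all 4 arrays, outlier spots kept, saturated probes left out, a trended robust prior, an unmoderated test per probe, a minimum change of 2-fold, the replicate number as a block, leaving out each array, and for lists fry, an estimated correlation and all probes of a gene. Chosen after seeing the data were scaling to the 10 E1A spike-in probes, a minimum mean signal of -4, the wider background, counts of 2-fold changes under every setting, 10000 random lists matched on signal, and a test of words in the descriptions. The figures were drawn from these values.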

Results

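Transcript levels were measured in seedlings of tobacco (*Nicotiana tabacum* cultivar Xanthi) that overexpressed OpAP2-3, named in the labels only as a line designation, and in seedlings that carried the vector alone. AP2/ERF proteins are a large family of plant transcription factors, many of which act in ethylene and stress responses. The seedlings were grown in pots for 2 weeks in a greenhouse, and 500 ng of total RNA per sample was labelled with Cy3 and hybridized to 4 arrays, 2 per group. Between 81.7% and 83.1% of the spots on each array were well above background, and none was saturated. The number of arrays limits the precision. Arrays of the same group correlated at 0.998 for the vector control and 0.997 for OpAP2-3 across tested probes, and arrays of different groups at 0.963 to 0.970. Probes are not independent replicates. Nothing in the labels says that the 2 arrays of a group came from separate plants, so the p-values below measure only the spread between these arrays, which may be technical.

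The comparison of OpAP2-3 overexpression with vector control asks which transcripts differ when this gene is overexpressed. No probe on the array was named OpAP2-3, so the level of the transgene itself was not measured here. The OpAP2-3 seedlings had far higher levels of NT16 polypeptide, Hairy root 4, a putative cinnamyl alcohol dehydrogenase and several class III peroxidases, the secreted enzymes that use hydrogen peroxide on cell wall phenolics. Of 28 class III peroxidases, 11 were higher and 7 lower by at least 2-fold. The same seedlings had far lower levels of apyrase, polyphenol oxidase, the hypersensitivity-related transcript HSR201, 3 lipoxygenase entries, pathogenesis-related protein 1B and acidic chitinase III. Several WRKY factors were also far lower. The dehydrin NtERD10A and 3 entries of the proline-synthesizing enzyme P5CS were higher, and the ligase 4CL1 and a 3-hydroxy-3-methylglutaryl coenzyme A synthase were lower.

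Of 36496 probes tested with limma, 20324 passed an adjusted p of 0.05, 12951 of them higher and 7373 lower in OpAP2-3 seedlings. At least 2-fold changes were passed by 3567 higher and 1847 lower probes, and 917 of these 5414 probes had an informative description. The balance of directions depended on how the arrays were scaled and on the dim probes. With quantile normalization in place of the 75th percentile, 1582 probes were higher and 2509 lower by at least 2-fold, which put the share of higher calls at 38.7% instead of 65.9%. The 2 scalings shared 1577 higher and 1845 lower probes. With the main scaling and a mean signal of at least -4, chosen after seeing the data, 1305 probes were higher and 1453 lower by at least 2-fold, a share of 47.3%. The median change over all tested probes was 0.21 on the log2 scale with the 75th percentile, 0.056 with quantile normalization, 0.35 after normexp background correction and -0.72 when the arrays were scaled to the spike-in transcripts, an alternative chosen after seeing the data. With that scaling 1429 probes were higher and 25634 lower. The labels do not say whether the spike-ins were added in equal amounts per RNA, which that scaling assumes, so directions are given here relative to the 75th percentile of each array. Without vector control replicate 1, 7108 probes passed, without vector control replicate 2 8590 probes passed, and without OpAP2-3 replicate 2 12258 probes passed.

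**Figure D1:**
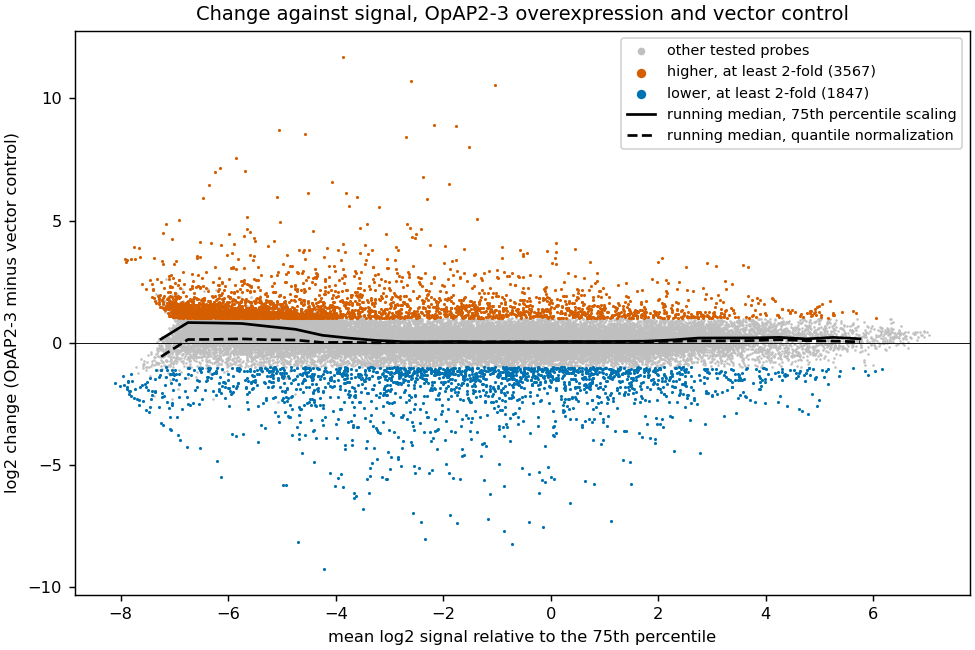
Log2 change of each tested probe (OpAP2-3 minus vector control, vertical axis) against its mean log2 signal relative to the 75th percentile of each array (horizontal axis), with 3567 higher and 1847 lower calls of at least 2-fold coloured and running medians drawn for both scalings. The solid median rises above 0 among the dimmest probes, where the median change was 0.80 at a signal of -6 or less and 0.62 between -6 and -4.

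Among the annotated probes whose arrays did not overlap between groups, the largest increase was that of NT16 polypeptide (TA21137_4097). It was not well above background on either vector control array and was at least 681-fold higher in OpAP2-3 seedlings (adjusted p = 0.000729). Bounds of this kind set the bright group's mean against the higher of the dim probe's own signal and the lowest signal among probes well above background. Hairy root 4 (AB035125) rose 481-fold, from a log2 signal of -6.62 ± 0.53 (SD, n = 2) to 2.29 ± 0.029 (SD, n = 2). A putative cinnamyl alcohol dehydrogenase (T114, AM851013), of a family that makes lignin alcohols, was higher by 8.44 on the log2 scale, with 1 of 2 vector control arrays above background. The putative annexin ann12 (AY965683), a calcium-binding membrane protein, was at least 37.9-fold higher. Among the peroxidases, anionic peroxidase swpb1 (EB445957) rose 90.7-fold with a standard error of 0.073 on the log2 scale, cationic peroxidase 38K (D42064) was at least 19.7-fold higher and a peroxidase precursor (CV021518) rose by 4.32 on the log2 scale. Isocitrate lyase (TA13482_4097), an enzyme of the glyoxylate cycle, rose 28.9-fold. Diguanylate cyclase (EB447376), a cDNA-AFLP fragment (AJ717912) and the urease accessory protein UreJ (EB442613) were not well above background in vector control seedlings and were at least 15.3-fold, 5.52-fold and 8.91-fold higher. Translationally controlled tumor protein (TA11974_4097) was higher by 4.16, with 1 of 2 vector control arrays above background.

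Among the same annotated probes, the largest decrease was that of a transcript described as sexual organ expressed protein (TA13877_4097). It was 95.4-fold lower in OpAP2-3 seedlings, from 3.65 ± 0.037 (SD, n = 2) to -2.93 ± 0.049 (SD, n = 2). Apyrase 3 (TA19568_4097), of a family that splits ATP, was 71.0-fold lower, and heme o synthase (TA12476_4097) 48.0-fold lower. Pathogenesis-related protein 1B (EH624149) and polyphenol oxidase (TC122902) had log2 changes of -6.15 and -6.14, each with 1 of 2 OpAP2-3 arrays above background. HSR201, a marker of the hypersensitive response, was 57.5-fold lower for 1 probe (EH620031) and 48.6-fold lower for another (X95343). A cysteine proteinase-like protein (TA21757_4097) was 50.5-fold lower, a lipoxygenase (TA16575_4097) 49.4-fold, the purple acid phosphatase NtPAP4 (AB017966) 48.0-fold, DNA-binding protein 4 (TA22119_4097) 45.0-fold and acidic chitinase III (Z11563) 39.6-fold lower. The adjusted p-values of these 12 transcripts lay between 0.000729 and 0.00389.

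**Figure D2:**
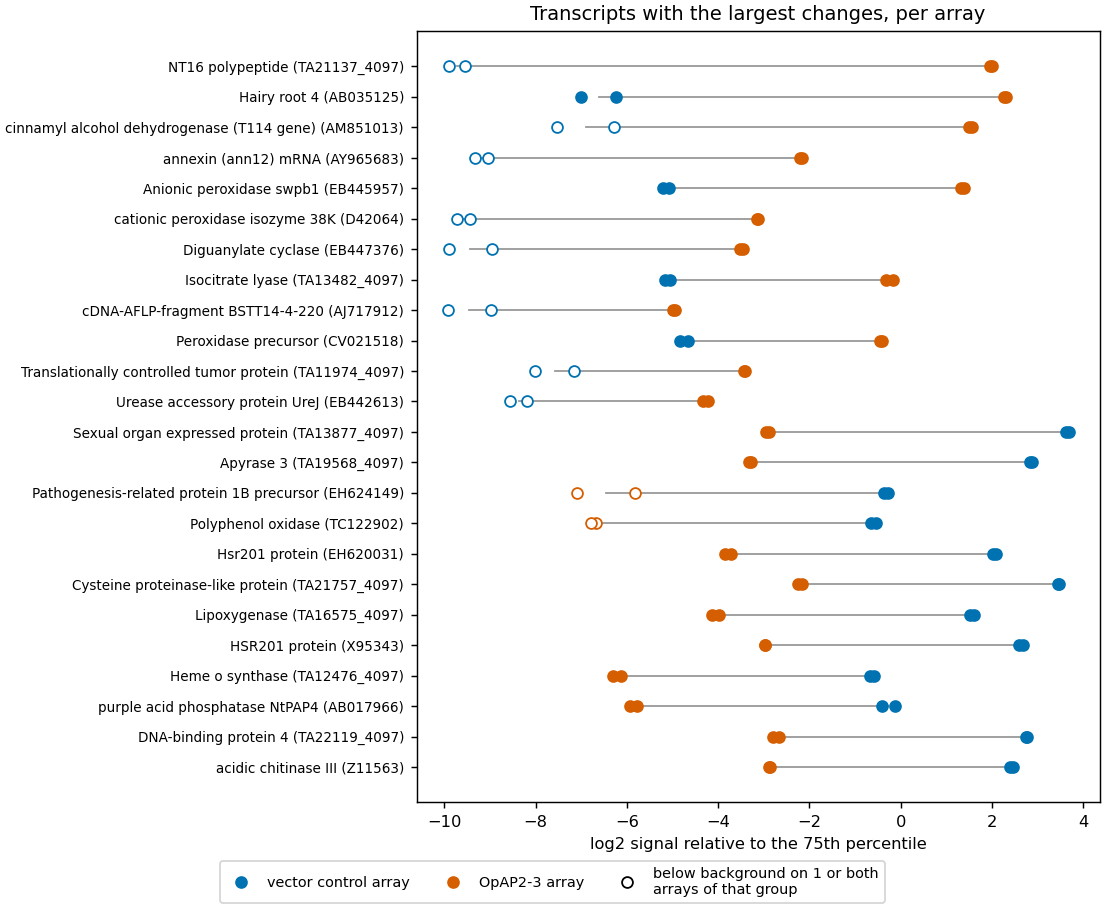
Log2 signal relative to the 75th percentile of each array (horizontal axis) for the 12 annotated transcripts with the largest increase and the 12 with the largest decrease, with 1 point per array and a line joining the group means. Open points mark groups in which 1 or both arrays were not well above background, and the vector control and OpAP2-3 arrays do not overlap for any transcript because the transcripts were chosen that way.

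The gene lists were fixed before the data were examined, and 32 of the 35 had enough measured genes for a test. With camera at a preset correlation of 0.01, 9 lists shifted against the other annotated genes after adjustment. None of the 9 held with an estimated correlation, where the smallest adjusted p was 0.58. The estimates for these lists ran from -0.036 for carbon fixation to 0.15 for light reactions. With 2 arrays per group that test has few residual degrees of freedom and could hardly call any list. It therefore cannot decide whether the 9 shifts hold. Under spike-in scaling the jasmonate, pathogenesis-related, phenylpropanoid, light reaction and ribosomal calls were lost, at adjusted p-values of 0.588, 0.222, 0.866, 0.588 and 0.862, and the nicotine and class III peroxidase lists were called upward, at 0.03 and 2.46e-05. That scaling moves every log2 change by the same amount, so the list medians against other annotated genes were the same under both scalings, as at -0.93 for jasmonate and 0.18 for ribosomal proteins. With all tested genes as the background, also chosen after seeing the data, 12 lists were called. That background lowers the list medians against it by about the same amount. For carbon fixation the median went from 0.395 to 0.258 and for WRKY factors from -0.178 to -0.315. The calls it gained and lost therefore reflect the background as well as the lists. The carbon fixation call was lost, at 0.0984, and glutathione S-transferases, WRKY factors, cell wall genes and the list of actin, tubulin, ubiquitin and EF-1 alpha were called downward, at 0.0193, 0.0411, 0.0167 and 0.0411. The list medians were also set against 10000 random lists of the same size matched on signal, a comparison chosen after seeing the data that treats genes as independent. Among the lists called downward, the medians lay at percentile 0 for jasmonate and light reactions, 0.83 for pathogenesis-related proteins, 0.43 for phenylpropanoids and 0.86 for terpenoids. Among those called upward, they lay at percentile 99.91 for LEA proteins, 99.92 for auxin, 99.99 for carbon fixation and 100 for ribosomal proteins. The uncalled cell wall, glutathione S-transferase and gibberellin lists lay as far out, at 0.01, 0.45 and 99.81. The counts below are of members past the threshold over all probes, and each entry of the array counts as a gene, although several entries can stand for the same gene.

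Jasmonate synthesis and signalling shifted down (camera adjusted p = 0.00576, adjusted p = 0.61 with an estimated correlation). Of its 21 members 4 rose and 14 fell, with the same counts when adjusted over the list alone. Entries described only as lipoxygenase had log2 changes of -4.52 (EB681141), -4.44 (EB430793) and -5.63 (TA16575_4097). Some lipoxygenases oxidize linolenic acid early in jasmonate synthesis, but the descriptions do not say whether these do. The jasmonate repressor NtJAZ1 (AB433896) fell by 3.67 ± 0.047 (SE). The median of the list was -0.85.

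Pathogenesis-related and antimicrobial proteins shifted down (camera adjusted p = 0.0212, adjusted p = 0.61 with an estimated correlation), with 8 of 42 members higher and 20 lower, or 9 and 20 when adjusted over the list alone. Acidic chitinase III was lower as given above, basic chitinase III (Z11564) was 12.4-fold lower and pathogenesis-related protein 4A (X58546) 8.43-fold lower. The fourth member named by the rule, the transcriptional activator PTI5 (TA16844_4097), was 4.60-fold lower and is a regulator of such genes. WRKY factors, transcription factors of defence, did not shift as a list against annotated genes (camera adjusted p = 0.271), with 8 of 24 members higher and 9 lower, or 8 and 10 when adjusted over the list alone. The 7 members that were lower by at least 2-fold included WRKY4 (AF193771, 17.8-fold), WRKY3 (AF193770, 14.2-fold), WRKY10 (AJ871280, 8.67-fold) and WRKY6 (CV016080, 20.4-fold), and no member was higher by at least 2-fold. A transcript described as DNA-binding protein 4 (TA22119_4097), a name the array also gives WRKY4, was 45.0-fold lower. Its description does not hold the word WRKY.

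Phenylpropanoid and lignin synthesis shifted down (camera adjusted p = 0.0212, adjusted p = 0.61 with an estimated correlation). Of 34 members 5 rose and 16 fell, with the same counts when adjusted over the list alone, and the list also holds the cinnamyl alcohol dehydrogenase that rose. The call was lost after normexp background correction (camera adjusted p = 0.0588). The median against other annotated genes was -0.282 in the main setting and -0.285 with normexp. The ligase 4CL1 (U50845), which activates coumarate, was 4.78-fold lower and hydroxycinnamoyl transferase (TA12691_4097) 5.01-fold lower. Terpenoid synthesis shifted down (camera adjusted p = 0.0124, adjusted p = 0.61 with an estimated correlation), with 3 of 23 members higher and 14 lower, or 5 and 14 when adjusted over the list alone. A 3-hydroxy-3-methylglutaryl coenzyme A synthase of the mevalonate pathway (TA14823_4097) was 7.35-fold lower and farnesyl pyrophosphate synthase (TA14923_4097) 3.32-fold lower. With all probes of a gene in the test, the terpenoid call was lost (adjusted p = 0.0676).

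LEA proteins and compatible solutes shifted up (camera adjusted p = 0.0212, adjusted p = 0.61 with an estimated correlation), with 13 of 21 members higher and 2 lower, and the same counts when adjusted over the list alone. The dehydrin NtERD10A (AB049335), a protein of drying tissue, rose 13.5-fold, and 3 entries of the proline-synthesizing enzyme P5CS (TA16466_4097, EB440509 and TA16465_4097) rose 4.59-fold, 4.42-fold and 4.72-fold. With all probes of a gene the call was lost (adjusted p = 0.0922). Abscisic acid genes, with 7 of 14 higher and 4 lower, did not shift as a list (camera adjusted p = 0.581), although the abscisic acid-inducible TAS14 (TA15607_4097) rose 14.1-fold.

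Auxin genes shifted up (camera adjusted p = 0.0208, adjusted p = 0.61 with an estimated correlation), with 20 of 32 members higher and 4 lower, and the same counts when adjusted over the list alone. An auxin-induced protein (TA19488_4097) rose 5.30-fold and the auxin-induced pCNT107 (X56266) 4.71-fold, while a SAUR-like transcript (EB427417) was 2.77-fold lower. Gibberellin genes did not shift as a list (camera adjusted p = 0.271), with 12 of 17 higher and 4 lower. The catabolic gibberellin 2-oxidase 5 (EF471118) was 3.97-fold lower and the biosynthetic gibberellin 3-oxidase 2 (EF471116) 3.32-fold higher.

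Photosynthetic light reactions shifted down (camera adjusted p = 0.0326, adjusted p = 0.71 with an estimated correlation), with 19 of 83 members higher and 39 lower, or 20 and 41 when adjusted over the list alone. Light harvesting chlorophyll a/b-binding proteins were 5.53-fold (TA11638_4097), 4.83-fold (CV018547) and 3.03-fold (TA11623_4097) lower. Carbon fixation and photorespiration shifted up (camera adjusted p = 0.0326, adjusted p = 0.61 with an estimated correlation), with 15 of 27 members higher and 3 lower, or 16 and 3 when adjusted over the list alone. Rubisco activase (U35111) rose 5.39-fold, whereas 1 carbonic anhydrase (TA12191_4097) rose 2.36-fold and another (TA16989_4097) was 1.95-fold lower. Without OpAP2-3 replicate 1 both calls were lost, at adjusted p = 0.0751 and adjusted p = 0.0621, and the carbon fixation call was also lost after normexp background correction (adjusted p = 0.107). Ribosomal proteins shifted up (camera adjusted p = 0.00171, adjusted p = 0.58 with an estimated correlation), with 123 of 237 members higher and 22 lower, and the same counts when adjusted over the list alone. The 4 with the smallest p were chloroplast proteins, among them S16 (TC164387), which rose 3.45-fold, and L12 (EB432877), which rose 2.51-fold.

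In the list for the family to which OpAP2-3 belongs by its name, 12 of 22 AP2/ERF members were higher and 1 lower. Its members were found by words in their descriptions, so it need not hold the whole family. The transcriptional activator PTI5 (TA16844_4097), 4.60-fold lower, is not in the list, since its description names no family. The counts therefore leave PTI5 out. The list missed the threshold (camera adjusted p = 0.0753). With a mean signal of at least -4, chosen after seeing the data, it passed upward (adjusted p = 0.0357), and its other camera settings gave 0.0544 to 0.612. The wound-responsive factor WRAF1 (AB274021) rose 6.71-fold, and ethylene-responsive transcription factor 1 (D38123) was 1.84-fold lower. Spike-in scaling lowers every log2 change by 0.93, so increases smaller than this turn by construction. The ethylene-responsive element binding protein 5 (EH623414) went from 0.78 to -0.15, and ethylene-responsive transcription factor 4 (TA13659_4097) from 0.93 to 0.0012. Of 28 class III peroxidases 13 rose and 11 fell, 11 of them by at least 2-fold upward and 7 downward, and the list was not called (camera adjusted p = 0.834). Under spike-in scaling it was called upward (adjusted p = 2.46e-05), with a median against other annotated genes of 0.056 in both scalings, and its other camera settings gave 0.643 to 0.958.

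**Figure D3:**
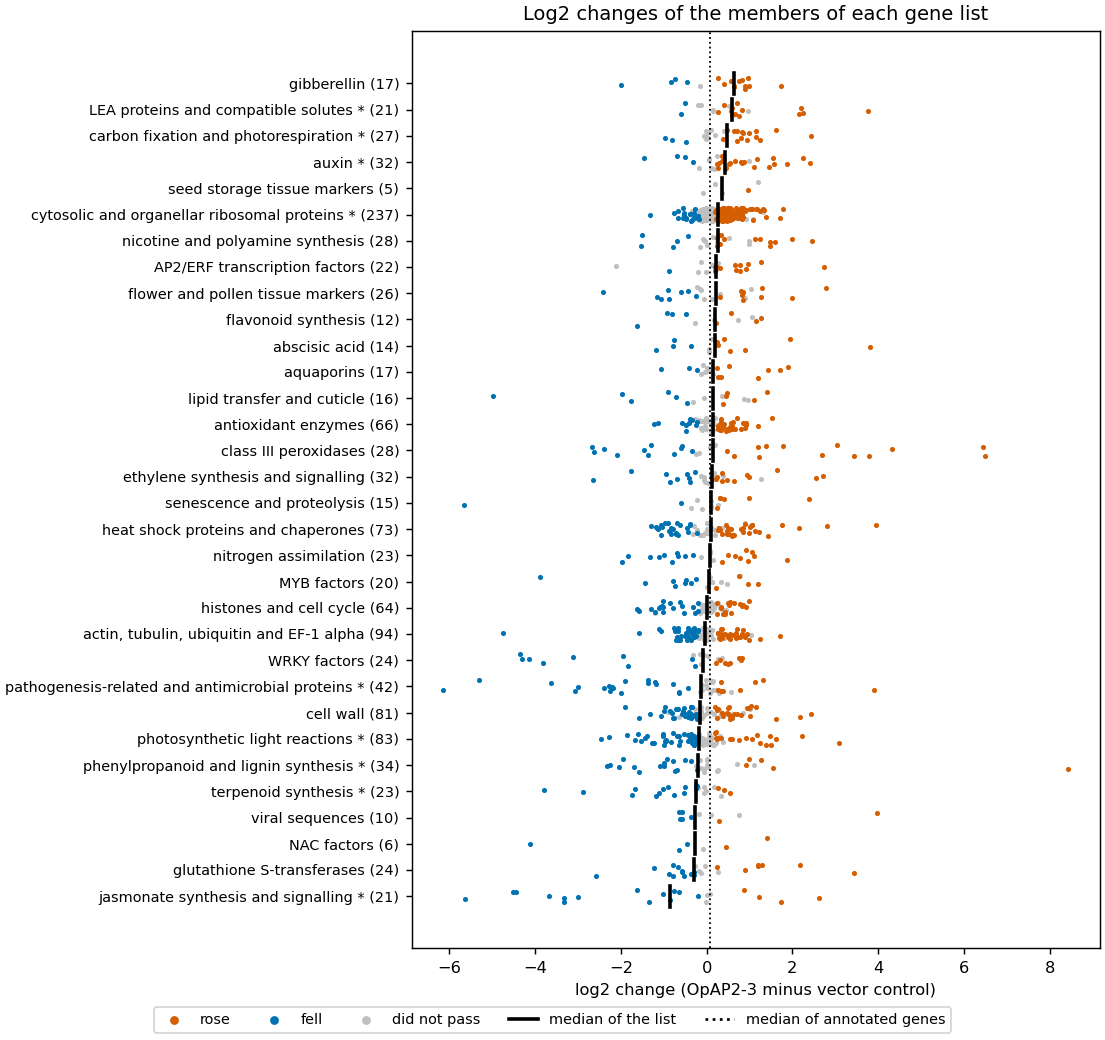
Log2 change (OpAP2-3 minus vector control, horizontal axis) of each measured member of the 32 tested gene lists, with the number of members in parentheses, bars at the list medians and asterisks at lists with a camera adjusted p below 0.05 at a preset correlation of 0.01. The jasmonate list lies lowest with a median of -0.85, and the dotted line marks the median of annotated genes, 0.083.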

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

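The E1A spike-in transcripts, control RNAs that the planned comparison did not use and only the added scaling did, were higher in the OpAP2-3 arrays than in the vector control arrays relative to the 75th percentile. All 10 spike-in probes were higher, by a median of 0.93 and between 0.56 and 1.02 on the log2 scale. The labels do not say whether equal amounts were added per RNA, so the cause of the difference stays open. The spike-ins were flagged as a signal outside the main measurement that lay above its level in the control arrays.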

How the results depend on the processing

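Spike-in scaling, the signal minimum and the 2-fold counts under settings other than the main one were chosen after seeing the data. The minimum change of 2-fold in the main setting was planned. In place of 20324 probes, 12567 passed an unmoderated test (7189 higher, 1782 by at least 2-fold). A minimum change of 2-fold left 5414 (3567 higher, 1847 lower). Leaving out each array gave 7108 to 16534 probes, 4021 to 11235 higher and 3087 to 5299 lower, and 1818 to 4719 higher by at least 2-fold, with the lone array assumed to vary like the other group. Normexp raised the higher calls to 19813. Quantile normalization gave 1582 and a mean signal of at least -4 gave 1305 probes higher by at least 2-fold, against 2509 and 1453 lower. Spike-in scaling gave 1429 higher and 25634 lower, 460 and 10969 of them by at least 2-fold. The 9 list shifts became 0 with an estimated correlation and 28 with fry, which does not compare a list with other genes. The causes were not tested. By construction a minimum change gives fewer calls, and the few residual degrees of freedom make calls with an estimated correlation hard to reach. No probe was saturated, so leaving saturated probes out moved nothing.

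With the replicate number as a block, 25309 probes passed and 9 lists shifted. Deviations of same-numbered arrays correlated at 0.47 across probes. With only 2 pairs, and nothing in the labels to say what the number marks, this does not establish pairing. The replicate number also follows the slide position inside each group, so a drift over positions could give such a correlation without pairing.

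Of 154 named probes, 116 kept direction and call in every setting that tested them, and 28 lost the call at a minimum change of 2-fold. Spike-in scaling lowers every log2 change by 0.93, so smaller increases reverse by construction. Reversed under it were EH623414 (-0.15), TA13007_4097 (-0.68), DV160620 (-0.46), TA21283_4097 (-0.35), EB679956 (-0.13), TA18682_4097 (-0.040), EB442954 (-0.030), TA20119_4097 (-0.18), TA12605_4097 (-0.47), TA13786_4097 (-0.17) and TA13467_4097 (-0.52). DV160620 also reversed with quantile normalization (-0.23), and EB427243 (0.54), TA20201_4097 (0.12) and DV159947 (0.13) with normexp. In fry the senescence list turned down and the flower list up, with medians of 0.026 and 0.14 against other genes. By signal, 88.3% of 2-fold calls were higher at -6 or less, 82.9% between -6 and -4 and 46.3% above 2.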

Other observations

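The tests of words, of slide position, of scaling among dim probes, of the spread and correlation between arrays and of the other splits were chosen after the result was seen, as were the camera tests with all tested genes as the background, spike-in scaling or a minimum signal. The other camera tests were planned, except for their background of annotated genes, which was chosen after the files were seen. Among words in the descriptions of genes changed at least 2-fold under both scalings, 5 of 484 tests passed Fisher's exact test after adjustment. "Pathogenesis-related" stood in 10 lower genes against 1.08 expected (adjusted p = 3.51e-06), "peroxidase" in 11 higher genes against 2.62 (adjusted p = 0.00967), "chlorophyll" in 11 lower genes against 2.81 (adjusted p = 0.01), "harvesting" in 6 lower genes against 0.936 (adjusted p = 0.018) and "isozyme" in 5 higher genes against 0.733 (adjusted p = 0.0497). The word "peroxidase" also stood in 7 lower genes against 3.6 expected, without passing (adjusted p = 0.683). These tests treat genes as independent.

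Other lists did not shift in camera against annotated genes. Heat shock proteins and chaperones had 28 of 73 members higher and 23 lower (camera adjusted p = 0.965), with the small heat shock protein Le-HSP17.6 (TA13599_4097) 7.04-fold higher. Glutathione S-transferases had 7 of 24 higher and 12 lower (camera adjusted p = 0.185), with a median of -0.28 and a mean of 0.019. Nicotine and polyamine synthesis had 13 of 28 higher and 5 lower (camera adjusted p = 0.444), with arginine decarboxylase 1 (AF127239) 2.36-fold higher and ornithine decarboxylase (TA13801_4097) 2.91-fold lower. Ethylene had 11 of 32 higher and 9 lower (camera adjusted p = 0.834), antioxidant enzymes 28 of 66 and 10 (0.271), flavonoids 4 of 12 and 4 (0.882), cell wall 25 of 81 and 31 (0.271), lipid transfer 5 of 16 and 6 (0.736) and aquaporins 8 of 17 and 3 (0.444). Nitrogen assimilation had 9 of 23 and 10 (0.736), senescence 6 of 15 and 2 (0.834), NAC 2 of 6 and 3 (0.39), MYB 4 of 20 and 8 (0.707), histones and cell cycle 18 of 64 and 20 (0.6) and actin, tubulin, ubiquitin and EF-1 alpha 28 of 94 and 34 (0.436). Of the tissue lists, flower and pollen had 9 of 26 higher and 8 lower (0.954), seed storage 1 of 5 and 0 (0.554) and virus-related host proteins 2 of 10 and 5 (0.39). With all tested genes as the background, chosen after seeing the data, glutathione S-transferases (0.0193), cell wall (0.0167) and the actin list (0.0411) were called downward, and under spike-in scaling nicotine and polyamine synthesis was called upward (0.03). Beside glutathione S-transferases, the median and the mean differed in sign for MYB, lipid transfer, nitrogen, senescence, histones, proteinase inhibitors and virus-related host proteins. For flavonoids, heat shock and flower both lay above 0 while camera pointed down. Proteinase inhibitors (3 of 4 higher, 1 lower) and cytokinin (1 of 4 higher, 1 lower) were too small to test, and no measured gene matched the root list.

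Dim probes were called higher far more often than lower, with 85.2% higher among 2-fold calls of the 12435 probes under a signal of -4. The step between neighbouring slide positions inside a group was 0.43 of the difference between the groups for these probes (95% bootstrap interval 0.419 to 0.44), and a steady drift over the 4 positions would give 0.5. The median change of these probes was 0.687, and -0.024 after taking off a drift of 2 steps. A shift that follows the array position could account for much of this excess, but position and group cannot be told apart by design. With quantile normalization the share of higher calls was 29.9%. That method gives every array the same distribution, so it removes a broad rise of dim probes whatever its cause, and scaling by a single percentile stays open. No biological explanation was tested.

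Bright probes differed little between the arrays of a group. The spread between arrays was 1.11 times the spread between spots of the same probe in vector control and 1.24 times in OpAP2-3 (95% interval 1.16 to 1.32), so it was somewhat above spot noise. The spot spread rests on 15 probes in each group, with 438 and 419 degrees of freedom. Only 11 non-control probes lie on 5 spots each, so control spots must enter it. Differences between the arrays correlated at 0.058 and 0.067 between 2 probes of a gene. Neither value decides whether the arrays held the same RNA or RNA of separate plants, since a spread between single arrays set against technical noise cannot show it.

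The 47 members of the jasmonate, pathogenesis-related, phenylpropanoid, terpenoid and WRKY lists with a log2 change of -1 or less, taken whatever their p, had a median change of -2.25, and all 47 were also past the threshold. Over all 144 members of these lists the median change was -0.237, and -0.408 after taking off a drift of 2 steps. For the 47 members, the step between slide positions was -0.00277 of the difference between the groups (95% bootstrap interval -0.00945 to 0.00537), where a steady drift over the 4 positions would give 0.5. This argues against a steady drift as the cause for these 47, and a jump between the positions of the 2 groups stays open, since position and group cannot be told apart by design. A state of the control seedlings, such as stress, stays open, since the study holds no second set of controls, and the effect of OpAP2-3 stays open as the biological explanation. Over the 3 splits of the 4 arrays into 2 and 2, the real one gave 20324 calls and the highest other 0, so it was the only 1 with as many. Each other split put arrays of both groups on each side, so the group difference entered its spread and few calls could result. With 3 splits a share under 0.05 also cannot be reached, so this contrast decides nothing.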
